A study of Mus musculus with 6 samples.

How the data were processed

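RNA was extracted on columns from mouse embryonic fibroblasts and made into libraries with version 2 of the TruSeq RNA kit, per the labels' protocols. That kit does not mark strand, so reads of overlapping antisense genes cannot be told apart. The authors deposited 1 table of raw counts per gene, with 24062 gene symbols and 1 column for each of the 6 libraries, and the counts are whole numbers with no normalization. Per the submitters' processing notes, the tools included TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6 and Subread, with the mm10 genome build. The gene annotation, the strand setting and the treatment of reads that match several places are not given in the sources used here. No row of the table lacks a gene name, no symbol occurs more than once, and 0 columns were left unmapped.

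Libraries were placed in groups by their titles, 3 in EV control and 3 in p27 OE. Total counts were 52098220, 34920728 and 49970661 in EV control 1, 2 and 3 and 44518389, 40338748 and 38533998 in p27 OE 1, 2 and 3. Replicates of a group differed by more than sampling noise: the mean chi-square per gene, near 1 for a library counted again, was 9.80 for the closest replicates, EV control 2 and 3, so none was taken for a repeat of another.

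Genes were kept with edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 14090, and scaled by TMM. CPM values use these scaled library sizes. Differences were tested with edgeR 4.0.16 (quasi-likelihood F test, robust fit, two-sided, Benjamini-Hochberg adjustment over all tested genes, threshold 0.05) in R 4.3.3. The fit fixed before the data were examined had no term for the replicate number. The standard error of a log2 fold change was taken from its F statistic. A second fit, also planned, had the replicate number as a block. Whether the numbers pair the libraries was checked from the correlation of each library's deviations from its group mean, in log2 CPM with a prior count of 2. It was 0.77, 0.42 and 0.54 between the libraries numbered 1, 2 and 3, each above 0.1, and each library correlated best with the one of its own number in the other group, although EV control 2 and p27 OE 3 also correlated at 0.39 and EV control 3 and p27 OE 2 at 0.41. The pairing thus comes from the shared numbers in the titles, together with this check for number 1. For numbers 2 and 3 the check cannot decide, since libraries of different numbers correlated about as well. The paired fit, with 535 genes higher and 512 lower, is given beside the unpaired one.

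Gene lists, 27 in number, were fixed before the data were examined and cover the cell cycle, CDK inhibitors, p53 targets, quiescence, secretory factors, matrix and contractile genes, interferon, metabolism and stress, and markers of other cell types. They were tested with camera in limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 26 lists with at least 3 tested members. Cdkn1b was left out of each list. By a rule also fixed beforehand, the genes named are Cdkn1b, a panel of 15 genes, the 10 with the largest increase and the 10 with the largest decrease among called genes with a mean of at least 5 CPM and the 3 libraries of one group on the same side of the 3 of the other, and for each list the 3 members with the smallest p and the called member with the largest change. The rule was written for the fit without pairing. Because that fit called 0 genes, the calls, the sizes and the ranking of list members were taken from the paired fit, a decision made after the data were examined. Ranked without pairing, the lists give 76 members, of which 47 are also named from the paired fit and 46 are called in it. The called ones appear with their group. For the largest changes a looser condition, the same direction in each pair, was also tried after the values were seen, and genes it adds are given apart. A gene outside the rule is said to have been chosen after its values were seen.

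Other settings fixed beforehand were RLE and upper-quartile scaling, no filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, leaving out each library, a test against a fold of 1.5, leaving out Cdkn1b, and for the lists an estimated correlation and fry. The same settings combined with the block, leaving out both libraries of a number, and a correction for transcript length and GC content were added after the data were examined. That correction removed from each library a loess trend (span 0.3) over length and GC content, taken from the GENCODE annotation of GRCm38, the assembly that mm10 names, in which 13963 of the tested genes were found. With 3 libraries against 3, an exact permutation test of one value cannot give a p under 0.1, so none was used.

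The fits were tested on simulated counts for this comparison with the real library sizes, means that kept the differences between numbers, and 200 changed genes, run on 13903 genes. Of 50 genes per size, the paired fit recovered 21 at 1.25-fold, 36 at 1.5-fold, 49 at 2-fold and 48 at 4-fold with 12 false calls, and the unpaired fit recovered 0, 0, 29 and 35 with 0 false calls. In the first simulation of camera, on 14090 genes, the lists could hold changed genes, and 1 of the 26 lists meant to be unchanged was called beside the 1 list that was raised. The changed genes were then taken out of the lists, after which camera called the raised list and 0 of the others. Apart from the differences between numbers, which were the same in both groups, the simulated genes varied independently. The simulation therefore cannot show how often camera calls an unchanged list whose members vary together from library to library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.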

Results

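RNA was sequenced from mouse embryonic fibroblasts, primary connective tissue cells grown from embryos of the C57BL/6 strain. One group had received a lentivirus that overexpresses p27 (p27 OE), the cyclin-dependent kinase inhibitor encoded by Cdkn1b, and the other is the EV control, an abbreviation the labels do not spell out. Each group had 3 libraries at day 4, a time at which the labels call the p27 OE cells not yet senescent. Total counts per library ran from 34920728 in EV control 2 to 52098220 in EV control 1, and 14090 of the 24062 genes in the table had enough counts to be tested. The comparison addressed what p27 by itself does to the transcriptome of cells that have not entered senescence. Libraries are named by group and by the number in their label. The labels do not say that the numbered libraries came from separate cultures, so p-values without pairing measure the spread between these libraries. In the paired fit they measure the spread of the differences between the groups within each number. Both edgeR fits also draw the variance of a gene toward a trend over all genes. Their p-values and SE thus do not rest on the libraries or pairs of that gene alone. The titles of the EV control libraries carry a dataset number, 10, that the p27 OE titles lack, and the labels do not say whether the groups were grown and sequenced together.

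Cdkn1b was higher in each p27 OE library than in each EV control library. It stood at 52.2, 49.9 and 51.2 CPM (counts scaled by library size) in EV control 1, 2 and 3, and at 419, 978 and 460.0 CPM in p27 OE 1, 2 and 3. The ratio within the libraries of one number was 8.02, 19.6 and 8.99. The gene lies on chromosome 6 from 134920401 to 134925513 on the forward strand (GRCm38), and its counts do not separate the endogenous transcript from that of the vector. The edgeR log2 fold change was 3.60 ± 0.35 (SE, n = 3 per group) with an adjusted p of 0.180. In the paired edgeR fit it was 3.48 ± 0.42 with an adjusted p of 0.0873, so edgeR with all 6 libraries called the overexpressed gene in neither fit, and limma-voom without pairing gave 0.0847. p27 OE 2, with more Cdkn1b than the other p27 OE libraries, set that spread: without it the log2 fold change was 3.11 and the edgeR adjusted p 0.00105, and DESeq2 gave an adjusted p of 4.70e-28 with all 6 libraries.

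**Figure D1:**
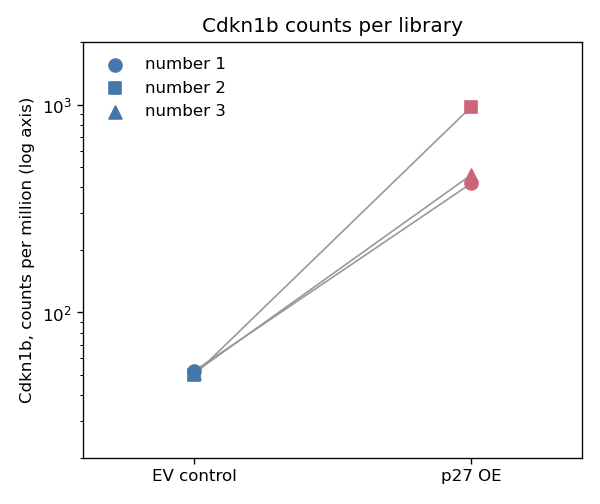
Cdkn1b CPM (log axis) in each of the 6 libraries, with a grey line joining the libraries of one number. The EV control libraries lie between 49.9 and 52.2 CPM and the p27 OE libraries between 419 and 978 CPM.

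Within pairs of libraries of the same number, 16 of 22 contractile genes rose in p27 OE and none fell, and of 45 extracellular matrix genes 16 rose, 6 fell and 23 were not called. With an estimated correlation the list tests gave an adjusted p of 0.330 and 0.722. Myc and the D-type cyclin genes Ccnd1 and Ccnd2 also rose. Cdkn1c, the gene of the related inhibitor p57, fell, as did the clock-controlled transcription factor gene Dbp, the lipoprotein lipase gene Lpl and the interferon regulatory factor gene Irf7. For example, the smooth muscle myosin gene Myh11 rose 2.11-fold (log2 1.08 ± 0.06, SE, n = 3 pairs) and Dbp fell 2.05-fold (-1.04 ± 0.13). In the paired edgeR fit, with the number as a block, 535 genes were higher and 512 lower in p27 OE out of 14090. Of these, 534 and 512 moved the same way in each of the 3 pairs. The fit calls genes for a steady difference within these same pairs, so that agreement is no separate support. The changes were small: the median size among called genes was 0.32 on the log2 scale, 169 of the 1047 reached 1.5-fold, and 35 higher and 11 lower genes reached 2-fold. The fit fixed beforehand, edgeR without pairing, called 0 genes. In it 1017 genes had an unadjusted p under 0.05, and DESeq2 without pairing called 29 higher and 16 lower, 43 of these 45 also among the paired calls. The paired count depended on the libraries: without both libraries numbered 3 it was 224 higher and 106 lower, and without those numbered 1 it was 893 and 848. With upper-quartile scaling it was 483 and 736, and a paired test against a 1.5-fold change called 3 and 0.

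The libraries numbered 1 stood apart from the other 4. The first principal component of log2 CPM held 58.9% of the variance and separated these from the rest, and the second held 17.2% and set the p27 OE libraries apart from the EV control libraries. Xist, the RNA that coats the inactive X chromosome, was at 317 CPM in EV control 1 and 477 CPM in p27 OE 1, against 5.93 and 9.57 CPM in the libraries numbered 2 and 0.601 and 0.504 CPM in those numbered 3. The Y-linked gene Ddx3y was at 0.0556 and 0.0220 CPM in the libraries numbered 1 and between 54.3 and 65.5 CPM in the other 4.

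**Figure D2:**
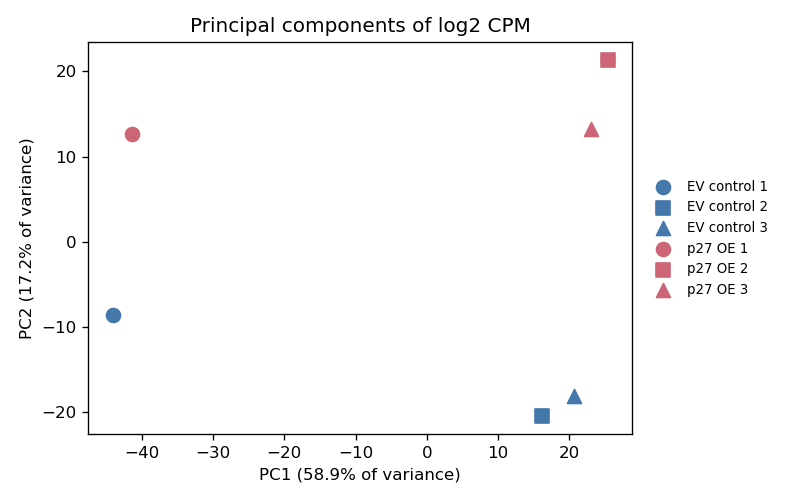
First and second principal components of log2 CPM over the 14090 tested genes, 1 point per library, coloured by group and with a marker shape for each number. The libraries numbered 1 lie at -44.1 and -41.4 on the first component, and the p27 OE libraries lie above 0 and the EV control libraries below 0 on the second.

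All values from here on are from the paired edgeR fit unless stated, as log2 fold change ± SE over n = 3 pairs. The SE comes from the fit and is not the SE of the 3 ratios of a gene. Paired fits without the libraries of a number rest on 2 pairs, and their adjusted p are unstable. For Cdkn1b it was 0.0873 with all pairs and 1.46e-69 without the libraries numbered 2. A call gained or lost in such a fit is therefore weak evidence. Among called genes with a mean of at least 5 CPM and groups that did not overlap, the 10 with the largest increase were Col10a1, Serpinb9b, Myh11, Coch, Myom1, Fn1, Hist1h2bc, Des, Uchl1 and Gpr116. Col10a1, the collagen of hypertrophic cartilage, rose from 15.1 ± 1.09 to 35.9 ± 2.73 CPM (mean ± SD; 1.25 ± 0.07, adjusted p 7.34e-07). Its adjusted p of 0.0799 was the smallest in the fit without pairing. Myh11 rose from 50.8 ± 8.33 to 107 ± 8.33 CPM, Fn1, fibronectin, from 8738 ± 2022 to 15322 ± 1484 CPM (0.83 ± 0.08, adjusted p 0.000196) and Des, the muscle intermediate filament gene, from 107 ± 21.2 to 175 ± 39.3 CPM (0.69 ± 0.06). The others were the protease inhibitor gene Serpinb9b (1.16), Coch (1.07), the sarcomere gene Myom1 (0.94), the histone gene Hist1h2bc (0.80), the ubiquitin hydrolase gene Uchl1 (0.69) and the receptor gene Gpr116 (0.67, adjusted p 0.0535 and 0.0860 without the libraries numbered 2 or 3).

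The 10 with the largest decrease under the same conditions were Dbp, Ramp3, Fbxo2, Lpl, Sord, Irf7, Gstm1, Serpinb8, Gstt1 and 6330403K07Rik. Dbp fell from 15.7 ± 4.19 to 7.48 ± 0.600 CPM (adjusted p 0.000908), and Lpl from 22.4 ± 3.02 to 12.8 ± 0.843 CPM (-0.80 ± 0.11, adjusted p 0.00127). Irf7 changed by -0.77 ± 0.13, Sord, sorbitol dehydrogenase, by -0.78 ± 0.10, and the glutathione transferase genes Gstm1 and Gstt1 by -0.73 ± 0.07 and -0.71 ± 0.12. The receptor activity-modifying protein gene Ramp3 (-0.89) and Serpinb8 (-0.72) had adjusted p of 0.0844 and 0.0765 without the libraries numbered 3. Fbxo2 and 6330403K07Rik changed by -0.83 and -0.70. In other genes with changes as large the groups overlapped while the 3 pairs moved one way, and these were added after their values were seen, although Acta1 and Cdkn1c are also named from their lists. They include Acta1, skeletal muscle actin, which rose from 38.0 ± 17.0 to 98.7 ± 44.5 CPM (1.38 ± 0.06, adjusted p 4.15e-08), the lubricin gene Prg4 (1.10), Cmah (1.16), the potassium channel subunit gene Kcnmb1 (0.86, adjusted p 0.0590 without the libraries numbered 3), and, lower, Cdkn1c, Chchd10 (-0.84), Mab21l1 (-0.77) and Olfml1 (-0.74). Cdkn1c fell from 146 ± 67.3 to 86.0 ± 39.5 CPM (-0.76 ± 0.06, adjusted p 1.54e-05), with ratios of -0.76, -0.65 and -0.87 in pairs 1, 2 and 3.

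**Figure D3:**
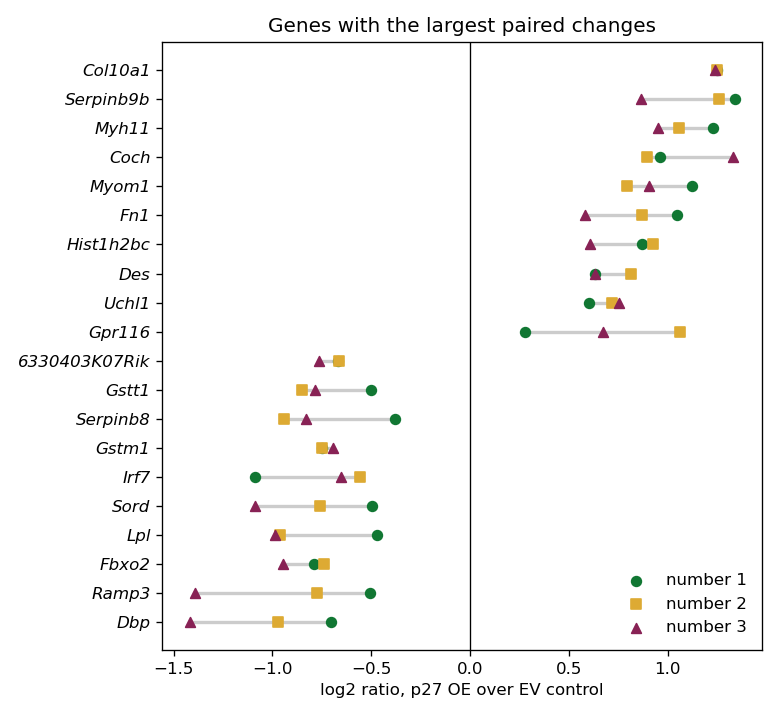
Log2 ratio of p27 OE over EV control within each pair of libraries of one number (1 marker per pair) for the 10 genes with the largest increase and the 10 with the largest decrease in the paired fit among called genes whose groups do not overlap. Col10a1 lies between 1.24 and 1.25 and Dbp between -1.42 and -0.70, and each of the 20 genes lies on one side of 0 in the 3 pairs.

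Among 22 contractile and myofibroblast genes, 16 rose and 0 fell (17 and 0 adjusted over the list alone). Besides Myh11 and Des these included the matricellular gene Ctgf (0.70 ± 0.06), the enteric actin gene Actg2 (0.66 ± 0.06) and the tropomyosin gene Tpm2 (0.27 ± 0.06, adjusted p 0.199 without the libraries numbered 3). Acta2, smooth muscle actin, chosen after its values were seen, rose by 0.22 (adjusted p 0.0403, and 0.319 without the libraries numbered 3). Limma camera called the list higher without pairing (adjusted p 1.81e-06) and with it (3.97e-09), but the adjusted p was 0.507 and 0.330 with an estimated correlation. The list's median ratio was 0.22, 0.30 and 0.31 in pairs 1, 2 and 3. Of its members 17 and 0, 14 and 0, and 8 and 0 were higher and lower without the libraries numbered 1, 2 or 3. Of 12 skeletal muscle markers, Acta1 and Des rose and the other 10 were not called.

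Among 45 extracellular matrix genes, 16 rose and 6 fell (16 and 8 adjusted over the list alone). Besides Fn1, the tenascin gene Tnc rose by 0.77 ± 0.07, the elastin gene Eln by 0.55 ± 0.06, the fibrillin gene Fbn1 by 0.54, Ecm1 by 0.34 and the thrombospondin gene Thbs1 by 0.58. The fibulin genes Fbln1 (-0.51) and Efemp1 (-0.48) were among the members that fell. Thbs1, Fbln1 and Efemp1 were chosen after their values were seen. Camera called the list higher (adjusted p 0.00177 without pairing, 0.00885 with it), with an adjusted p of 0.467 and 0.722 with an estimated correlation, and the paired value was 0.190 without the libraries numbered 2. Of 12 chondrocyte and osteoblast markers, Col2a1 (0.77 ± 0.06), the aggrecan gene Acan (0.59 ± 0.09) and the osteopontin gene Spp1 (0.51 ± 0.09; adjusted p 0.0564 without the libraries numbered 3) rose and none fell.

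Few cell cycle genes were called. Of 40 DNA replication and S phase genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone): the E-type cyclin genes Ccne2 (0.81 ± 0.18) and Ccne1 (0.24 ± 0.06), which bind the kinase that p27 inhibits, and the thymidine kinase gene Tk1 (0.35 ± 0.08). Without the libraries numbered 3 these 3 had adjusted p of 0.0722, 0.304 and 0.159, and without those numbered 2 Ccne1 had 0.0584. Of 40 G2 and mitosis genes 2 fell (1 adjusted over the list alone): the phosphatase gene Cdc25b (-0.43 ± 0.07) and the centromere histone gene Cenpa (-0.26 ± 0.07, lost without the libraries numbered 2 or 3 at adjusted p 0.177 and 0.277). None of 24 DNA repair and checkpoint genes was called. The median ratio in pairs 1, 2 and 3 was 0.07, -0.09 and 0.07 for the S phase list, 0.08, -0.18 and 0.01 for the mitosis list and 0.14, -0.10 and 0.13 for the repair list. The numbers higher and lower without the libraries numbered 1, 2 or 3 were 3 and 2, 3 and 0, and 0 and 0 for S phase, 0 and 3, 3 and 1, and 0 and 1 for mitosis and 0 and 0, 2 and 0, and 0 and 0 for repair. Camera called none of the 3 (adjusted p 0.595, 0.595 and 0.465 without pairing). Leaving out single libraries changed this: the S phase list was called higher without EV control 1 (adjusted p 0.00685) or p27 OE 2 (0.0203) and lower without p27 OE 1 (0.00850). Without p27 OE 1 the mitosis list was called lower (0.000303), and the repair list was called higher without EV control 1 (0.0226) or p27 OE 2 (0.0232). With pairing and without the libraries numbered 2, the S phase and repair lists had 0.0215 and 0.00992, both higher. The proliferation marker Mki67 was at 66.1 ± 6.47 CPM in EV control and 84.1 ± 30.7 CPM in p27 OE (0.30 ± 0.14, adjusted p 0.304). Without the libraries numbered 2, with 2 pairs left, the adjusted p of Mki67 was 0.00585.

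Of 20 CDK inhibitors, pocket proteins, D cyclins and CDKs, Ccnd2 (0.44 ± 0.06) and Ccnd1 (0.40 ± 0.06) rose and Cdkn1c fell (3 and 2 adjusted over the list alone). Cdkn1a, which encodes p21, was at 440.2 ± 88.5 CPM in EV control and 428 ± 95.9 CPM in p27 OE (-0.05 ± 0.06, adjusted p 0.703). Cdkn2a differed by 0.09 ± 0.07, Cdkn2b by 0.11 ± 0.07, the retinoblastoma gene Rb1 by -0.04 ± 0.12 and Skp2, a subunit of the ligase that degrades p27, by -0.04 ± 0.08, none of them called. The nuclear lamina gene Lmnb1 (-0.18 ± 0.07) and the chromatin protein gene Hmgb2 (0.02 ± 0.06), whose loss marks senescent cells, were not called either, but Lmnb1 had an adjusted p of 0.0337 and Cdkn2b of 0.0400 without the libraries numbered 1. Trp53 rose by 0.26 ± 0.07 (adjusted p 0.0360, and 0.127 or 0.247 without the libraries numbered 2 or 3). Of 30 p53 targets 2 rose and 2 fell (3 and 2 adjusted over the list alone), among them Plk2 (0.37), Pmaip1 (0.34) and Sesn1 (-0.38), and none of the 4 was called without the libraries numbered 3. Of 23 quiescence and FOXO-related genes none rose and 5 fell (1 and 7 adjusted over the list alone), including Cdkn1c and the growth arrest-specific genes Gas1 (-0.61 ± 0.07) and Gas2 (-0.33 ± 0.06), and Pmp22 (-0.27 ± 0.05, adjusted p 0.159 without the libraries numbered 3). The numbers higher and lower without the libraries numbered 1, 2 or 3 were 3 and 2, 3 and 1, and 2 and 1 for the CDK list, 3 and 3, 2 and 1, and 0 and 0 for the p53 targets and 1 and 8, 0 and 5, and 0 and 4 for the quiescence list. Without pairing, camera called none of these 3 lists (adjusted p 0.595, 0.833 and 0.226), and with pairing only the quiescence list, lower, without the libraries numbered 2 (0.0282).

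The Myc and ribosome biogenesis list was higher by camera (adjusted p 1.81e-06 without pairing, 6.06e-06 with it, but 0.354 and 0.597 with an estimated correlation). Of its 27 genes 8 rose and none fell (13 and 0 adjusted over the list alone), and the numbers higher and lower were 8 and 0, 11 and 0, and 4 and 0 without the libraries numbered 1, 2 or 3. Myc rose from 46.5 ± 14.3 to 69.4 ± 24.4 CPM (0.56 ± 0.06, adjusted p 0.000220), and the nucleolar genes Nop56 and Ddx21 by 0.40 ± 0.06 and 0.31 ± 0.05. The polymerase I subunit gene Polr1a (0.32) and Nolc1 (0.23) also rose, Polr1a with an adjusted p of 0.0660 without the libraries numbered 1 and Nolc1 of 0.330 without those numbered 3. Of 14 tested replication-dependent histone genes 5 rose and none fell (8 and 0 adjusted over the list alone): Hist1h2bc rose from 23.8 ± 0.888 to 41.9 ± 6.13 CPM, the linker histone gene Hist1h1c by 0.56 ± 0.10, and Hist1h4h (1.55 ± 0.29) and Hist1h2ab (2.76 ± 0.51) rose from low levels, with EV control means of 0.496 and 0.0946 CPM. Camera called the histone list higher (adjusted p 1.09e-08 without pairing, 4.65e-08 with it, and 0.185 and 0.330 with an estimated correlation). Most members had low counts: with the filter of at least 1 CPM in at least 3 libraries, 5 were tested, of which 3 rose. Histone genes of a class have near-identical copies, and how reads that match several copies were counted is not given in the sources used here, so values of single histone genes are uncertain. Which forms of these transcripts the counted reads come from is not known here either. The rise is therefore not read as more DNA replication.

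Interferon-stimulated genes were lower by camera (adjusted p 1.37e-06 without pairing, 3.00e-06 with it, and 0.507 and 0.637 with an estimated correlation). Of 34 members 6 fell and none rose (16 and 1 adjusted over the list alone). The membrane restriction factor gene Bst2 fell from 75.6 ± 10.1 to 48.6 ± 10.2 CPM (-0.65 ± 0.07, adjusted p 0.000132), and the transcription factor genes Irf7 and Stat2 changed by -0.77 ± 0.13 and -0.35 ± 0.06. The list's median ratio was -0.64, -0.08 and -0.44 in pairs 1, 2 and 3. The numbers higher and lower were 2 and 5, 0 and 15, and 0 and 4 without the libraries numbered 1, 2 or 3. Of 21 antigen presentation and NK ligand genes only Psme1 was called (-0.27 ± 0.07, lost without the libraries numbered 1 or 3 at adjusted p 0.0803 and 0.0820), and camera did not call the list (adjusted p 0.167) except as lower without p27 OE 2 (0.00170) or, with pairing, without both libraries numbered 2 (0.00756), when 4 members fell.

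Of 42 senescence-associated secretory factors 8 rose and 2 fell (11 and 4 adjusted over the list alone), and the numbers were 9 and 3, 9 and 2, and 5 and 1 without the libraries numbered 1, 2 or 3. The activin subunit gene Inhba rose by 0.54 ± 0.06, and the binding protein genes Igfbp6 and Igfbp3 changed by -0.38 ± 0.06 and -0.29 ± 0.06 (Igfbp3 with an adjusted p of 0.177 without the libraries numbered 3). Timp1, an inhibitor of matrix proteases, rose by 0.45 ± 0.09 (adjusted p 0.0860 without the libraries numbered 3). Il6 was at 0.554 ± 0.134 CPM in EV control and 1.06 ± 0.296 CPM in p27 OE (adjusted p 0.0909). Of 18 chemokines Cxcl14 (0.29 ± 0.06) and Cxcl1 (1.78 ± 0.39, from a low EV control mean of 0.721 CPM) rose (3 and 0 adjusted over the list alone). Neither was called without the libraries numbered 3 (adjusted p 0.0597 and 0.167), nor Cxcl1 without those numbered 2 (0.219). The chemokines higher and lower numbered 5 and 0, 3 and 1, and 0 and 0 without the libraries numbered 1, 2 or 3. Ccl2 was at 206 CPM in p27 OE 2, at 16.2 and 18.2 CPM in p27 OE 1 and 3 and between 9.63 and 12.7 CPM in EV control (adjusted p 0.477). Without the libraries numbered 2, with 2 pairs left, the adjusted p of Ccl2 was 7.64e-07. The median ratio in pairs 1, 2 and 3 was 0.16, 1.55 and 0.12 for the chemokines, 0.17, 0.65 and 0.14 for the secretory factors and 0.27, 0.88 and 0.37 for 17 macrophage markers. Camera called these lists higher without pairing (adjusted p 0.0153, 0.00352 and 7.99e-07). None was called with an estimated correlation (0.515, 0.515 and 0.507). Without p27 OE 2 the adjusted p was 0.446, 0.518 and 0.000207, and the chemokines had 0.0501 without EV control 3. With pairing the adjusted p was 0.00885, 0.000326 and 1.08e-05 (0.637, 0.693 and 0.637 with an estimated correlation), and 0.0561 for the chemokines without the libraries numbered 2.

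Cholesterol synthesis genes were lower by camera (adjusted p 0.000742 without pairing, 0.00148 with it, 0.507 and 0.693 with an estimated correlation, and 0.154 without p27 OE 1). With pairing it was 0.0896 without both libraries numbered 1. Of 25 members 6 fell and 1 rose (10 and 1 adjusted over the list alone), among them Mvd (-0.40 ± 0.08), Fdft1 (-0.25), Insig1 (-0.26) and Pmvk (-0.27). Pmvk was not called when the libraries of any one number were left out (adjusted p 0.0564 to 0.124). The numbers higher and lower were 1 and 4, 1 and 3, and 0 and 7 without the libraries numbered 1, 2 or 3. Without those numbered 2, Fdft1 and Insig1 had adjusted p of 0.0615 and 0.122. Of 29 ER and integrated stress response genes Slc7a11 (0.57) and Calr (0.30) rose, neither of them without the libraries numbered 3 (adjusted p 0.0629 and 0.230). Of 36 lysosome genes 1, Ctsh (0.30), rose and 4 fell, among the latter Neu1 (-0.35) and Lipa (-0.22). Of 21 glycolysis genes Slc16a3 rose (0.24) and Aldoc fell (-0.61 ± 0.08), and of 25 immediate-early and handling stress genes only Hspa1a was called (-0.45). The lysosome calls, Slc16a3 and Hspa1a were lost without the libraries numbered 3. Slc16a3 (0.236), Hspa1a (0.109) and Ctsh (0.235) were also lost without those numbered 2. The numbers higher and lower without the libraries numbered 1, 2 or 3 were 7 and 1, 2 and 1, and 0 and 0 for ER stress, 2 and 4, 0 and 3, and 0 and 0 for lysosome, 4 and 1, 1 and 5, and 0 and 1 for glycolysis and 2 and 1, 0 and 0, and 0 and 0 for immediate-early genes. Adjusted over the list alone, 2 and 0 ER stress, 1 and 4 lysosome, 2 and 1 glycolysis and 0 and 1 immediate-early genes were higher and lower. Camera called none of these 4 lists without pairing (adjusted p 0.167, 0.226, 0.226 and 0.0814), and with it only the ER stress list (0.0284, 0.637 with an estimated correlation, and 0.140 or 0.153 without the libraries numbered 2 or 3). Without single libraries, camera called the lysosome list lower without EV control 1 (0.0324) or p27 OE 2 (0.0181), and the glycolysis (0.0298) and immediate-early (0.00688) lists higher without p27 OE 3. With pairing the lysosome list was lower without the libraries numbered 2 (0.0339) and the immediate-early list higher without those numbered 3 (0.0183).

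Among markers of other cell types, 1 of 17 macrophage markers was called, Emr1 (0.77 ± 0.20), at 2.06 ± 0.132 CPM in EV control and 3.64 ± 1.24 CPM in p27 OE. The abundant macrophage transcript Lyz2, chosen after its values were seen, was at 38.8 ± 4.75 and 40.4 ± 12.3 CPM (0.02 ± 0.10, adjusted p 0.924). In the endothelial (9 tested) and epithelial (7) lists 1 gene each rose, Emcn (0.93 ± 0.24) and Krt19 (0.41 ± 0.11). Emr1, Emcn and Krt19 were not called without the libraries numbered 2 (adjusted p 0.188, 0.0689 and 0.260) or 3 (0.0658, 0.226 and 0.120). Of 13 neural and Schwann markers Tubb3 (0.63 ± 0.08), Nes (0.63 ± 0.09) and Ncam1 (0.30 ± 0.06) rose, genes that fibroblasts also express, Ncam1 with an adjusted p of 0.0740 without the libraries numbered 3. Of 7 adipocyte markers only Lpl was called. Adjusted over the list alone, 2 macrophage, 1 endothelial, 3 epithelial, 2 skeletal muscle, 3 neural and 4 chondrocyte markers were higher, and 1 epithelial and 1 adipocyte marker lower. Without pairing camera called the macrophage list (above) and the adipocyte list, lower (adjusted p 0.0472, 0.106 with pairing and 0.467 with an estimated correlation; 0.220, 0.0634, 0.0696 and 0.0565 without EV control 1 and p27 OE 1, 2 and 3), and not the endothelial (0.643), epithelial (0.465), skeletal muscle (0.0966), neural (0.285) or chondrocyte and osteoblast (0.202) lists. With pairing it also called the skeletal muscle (0.00544) and chondrocyte and osteoblast (0.0376) lists higher, with an adjusted p of 0.597 and 0.637 with an estimated correlation, 0.0625 and 0.0920 without the libraries numbered 1, and 0.0717 for the chondrocyte list without those numbered 3. Without pairing these lists were called higher without p27 OE 3 (0.00309) and EV control 1 (0.0324) respectively. With pairing the adipocyte list was lower without the libraries numbered 2 (0.0339). The table holds 0 mitochondrially encoded genes, so that list was not tested.

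**Figure D4:**
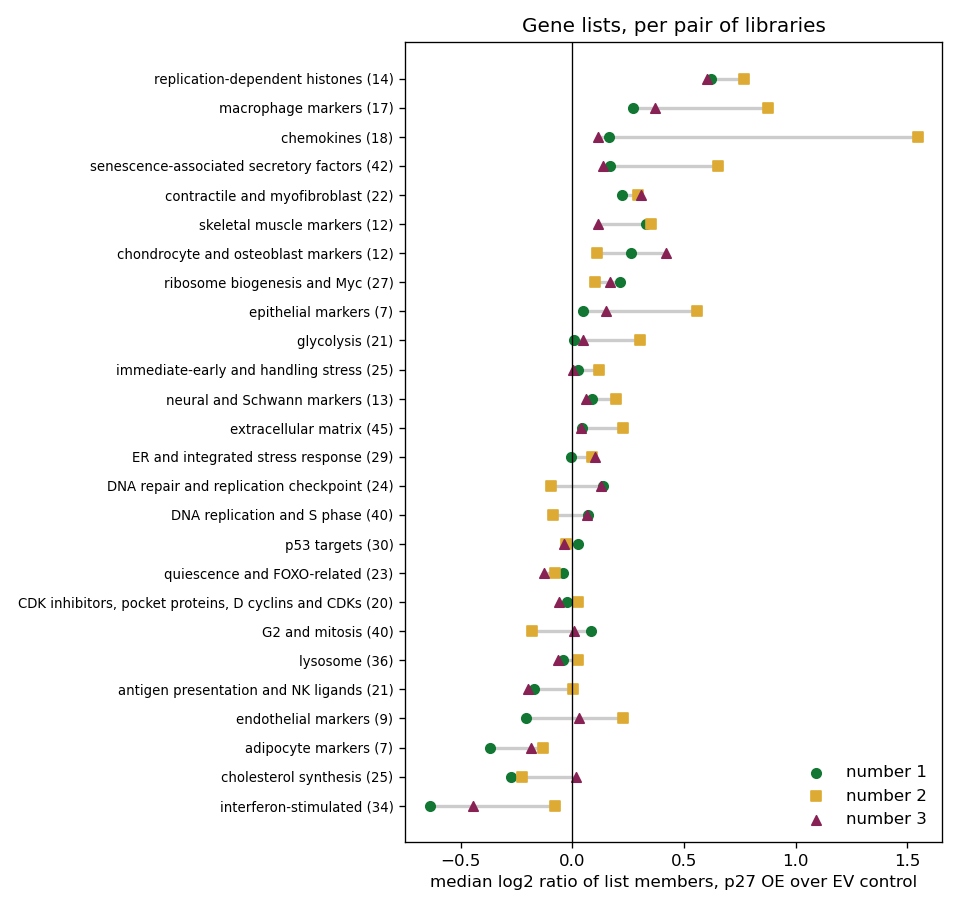
Median log2 ratio of p27 OE over EV control over the tested members of each of 26 gene lists (number tested in parentheses), 1 marker per pair of libraries of one number, with a grey line from the lowest to the highest pair. The chemokine list lies at 0.16, 1.55 and 0.12 in pairs 1, 2 and 3 and the contractile list at 0.22, 0.30 and 0.31.

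In all, camera with a preset correlation called 10 of 26 lists without pairing and 12 with it, and 0 in either case with an estimated correlation, where the smallest adjusted p was 0.185 without pairing. The limma rotation test fry, which asks whether the genes of a list move one way on balance, called the histone list without pairing (adjusted p 0.0261) and the contractile list with it (0.0270). Other ways of splitting the same 6 libraries into groups of 3 also gave up to 10 called lists.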

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

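Settings that combine the block with another choice were chosen after the data were examined, and the others were planned. Without pairing, the counts of 0 higher and 0 lower genes stayed at 0 under RLE and upper-quartile scaling, the CPM filter, limma-voom, the 1.5-fold test and without Cdkn1b. They became 1 and 0 with no filter, 29 and 16 with DESeq2, and 535 and 512 with the replicate block. Leaving out 1 library gave 0 to 1 higher genes (the 1 without p27 OE 2, Cdkn1b) and 0 lower. In the paired fit, scaling, filters, DESeq2 (455 and 345), limma-voom (457 and 372), leaving out Cdkn1b and the length and GC correction (663 and 517) stayed within 1.5 times of 535 and 512. The test against a 1.5-fold change called 3 and 0, and leaving out both libraries of a number gave 224 to 893 higher and 106 to 848 lower, the lowest without those numbered 3 and the highest without those numbered 1. The cause was not tested beyond the loss of libraries. Of the 1047 paired calls, 726 were also called by DESeq2 with the block, 837 with the length and GC correction and 288 without the libraries numbered 3. Each kept its direction in each setting that gave it a value, which adds little. These genes were called for a steady direction within pairs of the same counts, so a change of sign was unlikely. Upper-quartile scaling lowered the share of calls that were higher from 51.1% to 39.6%, with a shift of the median gene from -0.00118 to -0.0218 on the log2 scale.

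The Cdkn1b log2 fold change lay between 3.11 and 3.81 when 1 library was left out, and passed the threshold without p27 OE 2 and with DESeq2 (3.60). With the replicate block it was 3.48 and not called by edgeR (adjusted p 0.0873), but it was called by DESeq2, by limma-voom and by edgeR without the libraries numbered 2. The number of lists called by camera, 10, was 9 to 13 with 1 library left out and 12 with the replicate block, but 0 with an estimated correlation and 1 with fry. With the block, the 12 lists became 0 and 1 in the same 2 settings and 9 to 15 without a number. The S phase list turned from higher to lower without p27 OE 1 (adjusted p 0.00850). Slc2a1 and Egln3, not called in the paired fit, were lower without the libraries numbered 2 (-0.25 and -0.30). With an estimated correlation the adjusted p of the lists called without pairing was 0.185 (replication-dependent histones), 0.515 (senescence-associated secretory factors, chemokines), 0.467 (extracellular matrix, adipocyte markers), 0.507 (contractile and myofibroblast, interferon-stimulated, cholesterol synthesis, macrophage markers) and 0.354 (ribosome biogenesis and Myc). With fry it was 0.519 (senescence-associated secretory factors, chemokines), 0.159 (extracellular matrix, adipocyte markers), 0.504 (contractile and myofibroblast, interferon-stimulated, cholesterol synthesis, macrophage markers) and 0.107 (ribosome biogenesis and Myc). The replicate block changed the call of 4 lists, to 0.0284 (ER and integrated stress response), 0.00544 (skeletal muscle markers), 0.106 (adipocyte markers) and 0.0376 (chondrocyte and osteoblast markers), and of no other list. The CPM filter added 0.0307 (neural and Schwann markers). With 1 library left out, the adjusted p of the lists whose call changed ran over these ranges: DNA replication and S phase 0.00685 to 0.751, G2 and mitosis 0.000303 to 0.992, DNA repair and replication checkpoint 0.0226 to 0.992, senescence-associated secretory factors 6.64e-05 to 0.518, chemokines 8.32e-06 to 0.446, antigen presentation and NK ligands 0.00170 to 0.588, lysosome 0.0181 to 0.793, cholesterol synthesis 7.48e-07 to 0.154, glycolysis 0.0298 to 0.808, immediate-early and handling stress 0.00688 to 0.530, skeletal muscle markers 0.00309 to 0.233, adipocyte markers 0.0163 to 0.220 and chondrocyte and osteoblast markers 0.0324 to 0.918. At these depths the paired fit recovered 36 of 50 simulated 1.5-fold changes, and 21 of 50 at 1.25-fold, so smaller changes can have been missed.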

Other observations

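The groups of genes in the next 2 paragraphs were chosen after their values were seen, and values are from the paired edgeR fit. Of 17 circadian clock genes 4 fell and 3 rose. The output genes Dbp (-1.04), Tef (-0.34 ± 0.06) and Hlf (-1.46 ± 0.33) and the Period gene Per3 (-0.57 ± 0.10) were lower and Arntl, the activator whose peak falls opposite to theirs, was higher (0.46 ± 0.07), as were Ccrn4l (0.60) and Cry2 (0.23). Hlf was at low levels, with means of 1.41 CPM in EV control and 0.543 CPM in p27 OE. Nr1d1 (-0.21 ± 0.10) and Per1 (-0.03 ± 0.07) were not called, but Nr1d1 was lower without the libraries numbered 2 (-0.33, adjusted p 0.0138). The Arntl ratio was 0.40, 0.52 and 0.46 in pairs 1, 2 and 3, and, without the libraries numbered 3, Hlf, Ccrn4l and Cry2 had adjusted p of 0.0610, 0.0616 and 0.286 (Cry2 0.129 without those numbered 2). Per3 had an adjusted p of 0.0597 without the libraries numbered 3.

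Of 16 glutathione transferase genes, which encode detoxifying enzymes, 4 fell and none rose. Gstm1 fell from 35.8 ± 7.72 to 21.5 ± 4.38 CPM (-0.73 ± 0.07), and Gstt1 (-0.71), Gsta4 (-0.59, adjusted p 0.0571 without the libraries numbered 1 and 0.0784 without those numbered 3) and Gstk1 (-0.51, adjusted p 0.0529, 0.157 and 0.207 without the libraries numbered 1, 2 and 3) were lower too. Of 9 genes of histone variants 4 fell and none rose, among them H1f0 (-0.35 ± 0.05) and H2afz (-0.19 ± 0.05; adjusted p 0.236 and 0.230 without the libraries numbered 2 and 3). Of the replication-dependent histone genes 5 of 14 rose, with the limits on their counts given above.

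Tests chosen only after the result was seen, in the 3 paragraphs that follow, are the autosomal check, the macrophage reads, the p27 dose, the tests of the contractile and matrix genes and the splits of the unpaired count. The libraries of one number deviated together. For number 1, genes of the sex chromosomes alone do not account for it, since the correlation was 0.75 over autosomal genes. Nor does a length and GC trend, with 0.78 after its removal. For numbers 2 and 3 the checks gave 0.39 and 0.51 over autosomal genes, and 0.42 and 0.54 after the trend was removed. They cannot decide there, since libraries of different numbers also correlated over autosomal genes, at 0.39 (EV control 3 and p27 OE 2) and 0.36 (EV control 2 and p27 OE 3). Xist (317 and 477 CPM) was high and the Y-linked Ddx3y near 0 in both libraries numbered 1, and Ddx3y was at 54.3 to 65.5 CPM in the other 4, so number 1 came from cells of another sex than numbers 2 and 3. For numbers 2 and 3 a shared origin, such as one embryo or one day of culture, stays open. Xist stood at 5.93 and 9.57 CPM in the libraries numbered 2 and at 0.601 and 0.504 CPM in those numbered 3. That difference goes with a shared origin within a number but rests on 1 gene. Without pairing, the real split gave 0 genes and the highest of the other splits 1. Any split reaches a count of 0, so that all 10 of the 10 splits did so tests nothing. With the block, the real split gave 1047 genes and the highest of the other 3 splits that part each pair gave 0. For camera, 4 of the 10 splits gave 10 lists, the real one included, and 10 was the highest of the others. Those others exchange the groups of number 2, exchange the groups of number 3, or put both libraries of number 1 with p27 OE 2, and neither 10 nor 4 splits can give a share under 0.05. With the block, 1 of the 4 splits reached the real count.

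p27 OE 2 stood apart in chemokines, with a list median ratio of 1.55 in pair 2 against 0.16 and 0.12 in pairs 1 and 3. Genes regulated by NF-kB and by hypoxia also stood apart there, but these 2 groups were chosen after their values were seen, so their medians describe the culture and test nothing. Over 12 NF-kB-regulated genes the median ratio was 2.19 in pair 2 against 0.13 and 0.20, with Nfkbia at 162 CPM against 24.0 to 26.4 CPM in the other 5 libraries. Over 15 hypoxia-regulated genes it was 1.05 against -0.09 and -0.18, with Slc2a1 at 607 against 213 to 284 CPM. Reads from macrophages stay open: their marker list gained 7.58 CPM for each 100 CPM gained by the chemokine list, but that ratio is not known for macrophages here, and the markers too had their highest median in pair 2 (0.88). Lyz2 was at 53.1 CPM in p27 OE 2 against 41.8 CPM in EV control 2, a baseline that would hide a small share. A higher p27 dose may be the cause, as Cdkn1b was at 978 CPM there, but 1 library keeps dose and any other state of that culture from being told apart.

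Of the contractile and matrix lists, 32 members rose, which may be an effect of p27, while 6 matrix members fell and 23 were not called. A length and GC trend is argued against as the whole cause of the rise of these 32, since 31 were still called higher after its removal. The culture of number 2 alone is argued against, weakly, as the source of these calls. In a fit on the 2 pairs left without it, 14 of 22 contractile and 14 of 45 matrix members were called higher, against 16 and 16 with all pairs. The contractile calls depended more on number 3: without it the numbers were 8 and 14, and without number 1 they were 17 and 18. Calls in fits on 2 pairs are unstable. Whether the matrix list rose as a whole stays open. Its median was 0.0724 with all pairs and 0.0360 without number 2. Without number 2, 7 members were lower and camera no longer called it (adjusted p 0.190). A larger share of contractile cells and a higher level in each cell cannot be told apart in RNA from whole cultures: over the smooth muscle genes Myh11, Actg2, Lmod1, Cnn1, Acta2, Des and Smtn the log2 fold change ran from 0.0736 (Lmod1, not called) to 1.08 (Myh11), with Acta2 (0.319) and Smtn (0.218) not called without the libraries numbered 3, nor Smtn without those numbered 2 (0.0633).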
